A study of Mus musculus with 6 samples.

How the data were processed

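The deposited table holds 1 count per gene and barcode. The unit was taken as UMI counts: every value was a whole number, and the submitters' processing notes name kallisto 0.46.0 and bustools 0.39.3 and the mm10 build, with no role given here to either tool. The authors' table had already been limited to barcodes of at least 1000 counts, the lowest value found in the file, and its highest mitochondrial share was 9.154%. Each barcode name carries the title of its sample, and 0 barcodes fell outside the 6 samples. Of the 27378 gene IDs, 27359 had a symbol in the annotation used, GENCODE vM21 (GRCm38, mm10), and 19 did not.

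Barcodes with at least 500 genes and at most 10% mitochondrial counts were kept (17 removed). A barcode was removed as an index-hopped copy where the same sequence had over 10 times its counts in another library (256 removed). Scrublet, the planned doublet caller, called 18 barcodes (0.104%) and did not separate doublets, so none was removed by it. Instead, a barcode was removed as mixed where it carried markers of at least 2 lineages, each with at least 3 counts and at least 5% (10% in the higher-level alternative) of the level of that lineage's highest cluster (2787 removed, leaving 14302 cells). The index-hopping and mixed-barcode steps were chosen after seeing the data.

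Counts were scaled per cell and log-transformed, 2000 variable genes were reduced to 30 principal components (seed 0), and a graph of 20 neighbours, kept where neighbours overlapped by at least 1 in 15, was clustered by Leiden at resolution 1 with scanpy 1.11.5 and igraph 0.11.9. Marker sets scoring near a cluster's best one were candidates for its name. The cluster took the set whose class led most over other classes by markers among its 10 leading genes. Ties went to the set's own leading markers, then the score. The score had to be at least 0.2 with at least 3 markers detected. Markers of another class could not outnumber its own there. With no own marker there, the score had to exceed the next class clearly. A low-count cluster needed own markers and no others there. The marker sets were fixed before the data were examined; the scoring was revised after the clusters had been seen. Of 24 clusters 1, led by cell cycle genes, stayed unnamed. Names carry the ending "-like" because they rest on RNA alone.

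Class shares were tested with edgeR 4.0.16 quasi-likelihood fits on cell counts with library totals as offsets (11 classes). For genes, counts were summed per library and class, filtered with filterByExpr, scaled by TMM and tested with robust edgeR quasi-likelihood fits over all 6 libraries, 3 residual degrees of freedom. T-like cells, with 19 and 15 cells in healthy libraries, were fitted on the 4 tumour libraries, 2 residual degrees of freedom. At least 20 cells per library were required, which left out NK-like and dendritic-like cells. Genes and classes were called at adjusted p under 0.05 (Benjamini-Hochberg) within a contrast. DESeq2 1.42.0 gave a second count. A library split, with healthy replicate 1 beside the control libraries and healthy replicate 2 beside the Rbpj-deleted ones, was found in the data and fitted as a batch term in an alternative. Each tumour group lies wholly on 1 side, so that term rests on healthy replicate 2 against healthy replicate 1 alone. It sets control tumours against healthy replicate 1 only and Rbpj-deleted tumours against healthy replicate 2 only. The difference of the Rbpj contrast between classes was tested with limma 3.58.1. Control and Rbpj-deleted tumours were each compared with the same healthy libraries, so those contrasts share their chance values and their calls were not overlapped. No source used here says which mice entered which library, so p-values of genes and classes measure the spread between these libraries, which may be technical in part. Where a left-out library leaves 1 in its group, that library is assumed to vary like the others. With 2 libraries per group a permutation p cannot fall below 0.333. Log2 values are given ± SE and levels as CPM, the mean of 2 libraries.

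Gene lists (27) were fixed before the data were examined and tested with camera at a correlation of 0.01 where at least 5 members were tested, 123 tests in all; the estimated correlation was run beside it. Camera sets the members of a list against the other genes, so its p-values at the fixed correlation do not measure the spread between libraries. Oligodendrocyte, glial progenitor, astrocyte, neuron and erythroid RNA had fewer than 5 tested members. Named genes follow a rule set before the data were examined. It takes up to 10 largest rises and 10 largest falls with adjusted p under 0.05, at least 20 CPM in the higher group and non-overlapping libraries, and up to 4 members of smallest p per list; some of the genes it takes are not reported here. Predicted genes, ribosomal, mitochondrial, antigen receptor segment and sex-linked genes were left out of its first part. Where a contrast had 5 or fewer called genes, each is named. A fold against 0 counts uses a floor of 3 counts, and folds against 1 to 3 counts carry an exact counting interval. Genes with at least 20% of their 31-mers in another gene are given as uncertain.

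The fits were checked on simulated data with known changes (5 draws, 100 genes per fold). Unchanged genes had p under 0.05 in 4.72% to 4.93% of edgeR tests, and 10.4% to 15.1% of edgeR calls were false. A 4-fold change was found in 74.8% to 80.8% of genes in microglia-like, 59.8% to 62.4% in monocyte/macrophage-like and 75.4% in T-like cells. A 2-fold change was found in 26.8% to 29.4%, 4.6% to 5.6% and 15.2%. The test between classes found 16% of 4-fold changes, with 19.2% of its calls false, and a 4-fold change of the T-like share was called in 60 of 100 draws. The share draws used a fixed spread rather than that of these libraries, so they do not give the power of the share tests here. Apart from the fits, the libraries of a group were compared in case 1 was a copy of the other. They differed by more than counting error, with chi-square per degree of freedom of 107.2 in healthy brain, 34.9 in control and 96.8 in Rbpj-deleted tumours.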

Results

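Immune cells sorted as CD45+ from mouse brain were profiled with 10x 3' v3 chemistry in 6 libraries: 2 from healthy brain, 2 from control gliomas (Trp53 deleted, Rbpj intact) and 2 from gliomas lacking Trp53 and Rbpj, per the labels. The series design gives pools of 9 healthy brains, 15 control tumours and 9 Rbpj-deleted tumours, while the extraction protocol describes each mouse in 1 well. Early tumours were micro-dissected by the GFP of a Cre reporter, so every share below describes dissected and sorted material. The deposited file held UMI counts for 27378 gene IDs (mm10) in 17362 barcodes. Total counts were 55229031 and 17430763 in healthy replicates 1 and 2, 18217310 and 17978360 in control replicates 1 and 2, and 49252701 and 32731006 in Rbpj-deleted replicates 1 and 2. After filtering, 6362, 2417, 948, 502, 2293 and 1780 cells remained in the same order, with median counts of 5251, 6013, 9534, 9164, 7697 and 6650 per cell.

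Rbpj, the DNA-binding partner of the Notch receptors (ENSMUSG00000039191, mm10 chromosome 5:53466152-53657362), was read at 45.9 ± 18.5 CPM (counts scaled to a common library total) in healthy cells, 88.1 ± 6.74 in control tumours and 51.7 ± 11.8 in Rbpj-deleted tumours (SD, n = 2 libraries each). Trp53, which encodes the tumour suppressor p53 (ENSMUSG00000059552, chromosome 11:69580359-69591873), stood at 84.2 ± 3.60, 87.0 ± 13.8 and 86.5 ± 7.37 CPM. The labels place the deletions in the tumour and the sequenced cells are immune cells, so these levels do not check them. The Y-linked genes Ddx3y (ENSMUSG00000069045, chromosome Y:1260771-1286629) and Eif2s3y stood at 74.9 ± 1.48 and 40.8 ± 16.4 CPM in healthy cells, 84.4 ± 14.4 and 57.8 ± 7.78 in control tumours, and 16.2 ± 4.0 and 13.9 ± 2.91 in Rbpj-deleted tumours. Xist, the RNA of the inactive X chromosome, stood at 2.53 ± 1.64, 1.85 ± 1.13 and 2.56 ± 1.69 CPM. It was low in every library (12 to 157 UMIs), so its level does not tell the sex of the mice. The sex of the mice is not given in the sources used here and was not separated from the Rbpj contrast.

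T-like cells were 20.8% (exact 95% interval 18.2 to 23.5) and 21.1% (17.6 to 24.95) of the kept cells in the control tumour libraries. In healthy brain they were 0.299% (0.180 to 0.466) and 0.621% (0.348 to 1.02), and in Rbpj-deleted tumours 2.36% (1.77 to 3.06) and 5.28% (4.29 to 6.42). The intervals hold counting error only. All shares follow the removal of mixed barcodes, 1631 of which over all libraries paired myeloid with T or NK RNA. The T-like cells kept numbered 197 and 106 in control tumours and 54 and 94 in Rbpj-deleted tumours. The rise of T-like cells from healthy brain to control tumours was log2 5.52 ± 1.06 (SE, n = 2 libraries per group, edgeR adjusted p = 0.0099), the 1 called change among 11 classes. Microglia-like cells averaged 79.7 ± 0.799% (SD, n = 2) in healthy brain, 36.4 ± 14.4% in control tumours and 40.7 ± 15.9% in Rbpj-deleted tumours. Monocyte/macrophage-like cells averaged 14.4 ± 1.95%, 19.3 ± 4.26% and 36.6 ± 9.50%, NK-like cells 0.318 ± 0.428%, 7.75 ± 5.60% and 3.14 ± 1.04%, and dendritic-like cells 1.27 ± 0.308%, 5.34 ± 3.04% and 5.52 ± 1.76%. B-like cells averaged 1.60 ± 1.31%, 2.50 ± 1.84% and 0.808 ± 0.526%. Plasmacytoid dendritic-like cells were 34 of 948 and 0 of 502 (exact 95% interval up to 0.732%) in control tumours.

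No class passed edgeR between Rbpj-deleted and control tumours (0 of 11, and 0 by limma on logit shares). T-like cells alone had an unadjusted p under 0.05, with log2 -2.46 ± 0.92 (edgeR adjusted p = 0.319). Monocyte/macrophage-like cells stood at log2 0.92 ± 0.81 (adjusted p = 0.639) and NK-like cells at -1.31 ± 1.38 (adjusted p = 0.674). Between Rbpj-deleted tumours and healthy brain 0 of 11 passed edgeR, with 2 at unadjusted p under 0.05: T-like cells (log2 3.06 ± 0.96, adjusted p = 0.143) and dendritic-like cells (2.12 ± 0.90, adjusted p = 0.220). The same contrast had 0 calls by limma, and 1 by edgeR without healthy replicate 2. From healthy brain to control tumours NK-like cells stood at log2 4.69 ± 1.60 (adjusted p = 0.117), dendritic-like cells at 2.08 ± 0.91 (0.190) and microglia-like cells at -1.13 ± 0.84 (0.342). The T-like call was lost without healthy replicate 1 (0 classes), with T-like cells at log2 5.06 (adjusted p = 0.151). It stood beside 1 more without healthy replicate 2 and 2 more without control replicate 2.

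**Figure D1:**
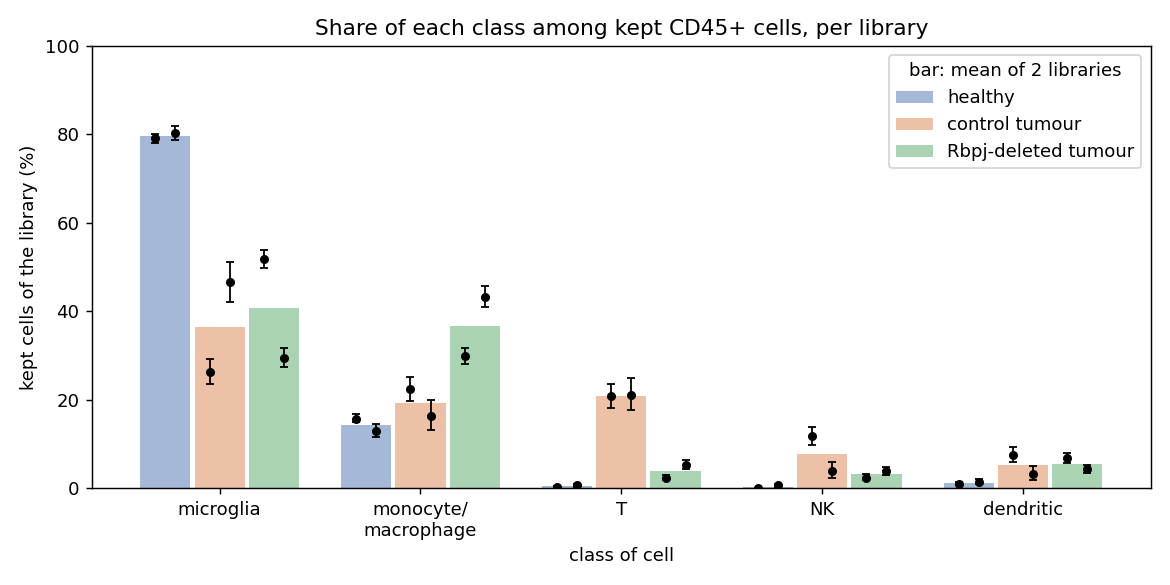
Share of kept cells (%, vertical axis) in 5 classes of cell; bars are means of 2 libraries, points are libraries with exact 95% binomial intervals. T-like cells sit at 20.8% and 21.1% in control tumours, against 0.299% and 0.621% in healthy brain and 2.36% and 5.28% in Rbpj-deleted tumours.

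Microglia-like cells of control tumours carried more interferon response and class I presentation RNA than those of healthy brain (camera adjusted p = 4.89e-68 for the interferon-gamma, 1.525e-66 for the type I interferon and 8.40e-43 for the class I list). With an estimated correlation camera gave adjusted p = 0.00643, 0.0247 and 0.0361 in the same order. H2-Aa, the alpha chain of an MHC class II molecule (ENSMUSG00000036594, chromosome 17:34282744-34287823), rose by log2 8.51 ± 0.55 (SE, n = 2 libraries per group), from 9.918 to 3615 CPM. Cd74, the invariant chain that guides class II molecules (ENSMUSG00000024610, chromosome 18:60803848-60812652), rose by log2 7.48 ± 0.50, and H2-Ab1, the class II beta chain, by 6.39 ± 0.66. The interferon-induced GTPases Iigp1 (log2 7.08 ± 0.37), Gbp4 (7.31 ± 0.49), Gbp2 (6.22 ± 0.38) and Gbp8 (5.61 ± 0.32) rose with Nlrc5, a transactivator of class I genes (5.57 ± 0.45). Serpina3f, a serine protease inhibitor (ENSMUSG00000066363, chromosome 12:104214544-104221129), had 249 UMIs against 0, at least 751-fold higher after scaling to the class total. The complement gene C4b rose by log2 7.01 ± 0.91, an uncertain value because 32.5% of its 31-mers occur in other genes. Ddit4, an inhibitor of mTORC1 signalling (ENSMUSG00000020108, chromosome 10:59949669-59951834), fell by log2 2.82 ± 0.47. Mycl, a MYC family gene, fell by 1.75 ± 0.25 and the transcription factor gene Sox4 by 1.41 ± 0.30. Falls were also seen for Mboat1 (1.76 ± 0.28), Myo18b (1.57 ± 0.26), Jam3 (1.37 ± 0.25), Ccdc80 (1.30 ± 0.28), Tmem44 (1.26 ± 0.23), Acvr2b (1.2 ± 0.22) and Lrba (1.18 ± 0.23).

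Of the interferon-gamma list, 18 of 19 tested genes rose in these microglia-like cells (adjusted over the list alone, 16 over all genes, camera adjusted p = 4.89e-68), Gbp5 among them by log2 3.37 ± 0.23. The type I interferon list had 26 of 27 up (adjusted over the list alone, 21 over all genes, camera adjusted p = 1.525e-66). Ifi204, a cytosolic DNA sensor family gene, stood at log2 4.68 ± 0.23, Oasl1 at 4.36 ± 0.29, Isg15 at 3.04 ± 0.27 and Bst2 at 2.36 ± 0.20. Class I presentation had 14 of 16 up (adjusted over the list alone, 12 over all genes, camera adjusted p = 8.40e-43), including the peptide transporter Tap1 (3.0 ± 0.22) and the proteasome subunit Psmb9 (2.13 ± 0.20). Class II presentation had 8 of 12 up (adjusted over the list alone, 6 over all genes, camera adjusted p = 4.64e-23, and adjusted p = 0.05 with an estimated correlation). H2-Oa stood at 3.06 ± 0.38. Of the inflammatory cytokine list 9 of 19 rose (adjusted over the list alone, 4 over all genes, camera adjusted p = 2.29e-19, and adjusted p = 0.0679 with an estimated correlation). The 4 were the chemokine genes Ccl12 (3.43 ± 0.26), Ccl7 (3.22 ± 0.34), Ccl2 (2.63 ± 0.37) and Cxcl16 (1.83 ± 0.20). Without a cluster led by Csf1, Egr3 and Tnf none of the 4 was called: Ccl7 turned to -0.10, and Ccl12 stood at 1.49, Ccl2 at 1.46 and Cxcl16 at 1.29. Of the disease-associated list 7 of 23 rose (adjusted over the list alone, 6 over all genes, camera adjusted p = 7.99e-12, and adjusted p = 0.103 with an estimated correlation), including the receptor kinase gene Axl (3.47 ± 0.28), the integrin gene Itgax (2.45 ± 0.29) and the lectin receptor gene Clec7a (2.24 ± 0.31). The complement list had 3 of 12 up, C3 at 3.38 ± 0.47 beside C4b and Cfb, both uncertain because 32.5% and 58.6% of their 31-mers are shared (adjusted over the list alone, 3 over all genes, camera adjusted p = 0.00215, and adjusted p = 0.108 with an estimated correlation).

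Lipid handling genes of these cells had 3 of 20 up (adjusted over the list alone, 3 over all genes, camera adjusted p = 6.79e-05, and adjusted p = 0.306 with an estimated correlation), the scavenger receptor gene Cd36 (4.61 ± 0.30) and Plin2 (1.35 ± 0.31) among them. Hypoxia and glycolysis genes had 4 of 14 up (adjusted over the list alone, 2 over all genes, camera adjusted p = 0.00404, and adjusted p = 0.391 with an estimated correlation). Pfkp stood at 3.02 ± 0.41. Cell cycle genes had 7 of 19 up (adjusted over the list alone, 1 over all genes, Top2a at 3.19 ± 0.43; camera adjusted p = 4.04e-05, and adjusted p = 0.262 with an estimated correlation). Homeostatic genes, several of which also named the class, fell as a list with 1 of 20 down (adjusted over the list alone, 0 over all genes, camera adjusted p = 0.000764, and adjusted p = 0.0819 with an estimated correlation). The alternative activation list did not pass camera (adjusted p = 0.611, 1 of 16 up, Il1rn at 4.95 ± 0.67), nor did the Notch list (adjusted p = 0.987, 0 of 12) or the dissociation and stress list (adjusted p = 0.556, 0 of 20). RNA of other cells moved too: Klrk1 (3.47 ± 0.63) and Nkg7 (2.80 ± 0.51) of the T and NK cytotoxicity list (7 of 9 up over the list alone, camera adjusted p = 6.47e-07, and adjusted p = 0.0735 with an estimated correlation), and Pdcd1 (3.79 ± 0.43) of the exhaustion list (4 of 10 up over the list alone, 2.45e-05, and adjusted p = 0.180 with an estimated correlation). The monocyte genes Ms4a4c (3.19 ± 0.27) and Plac8 (3.21 ± 0.27) rose with 3 of 5 of their list (camera adjusted p = 1.30e-07, and adjusted p = 0.05 with an estimated correlation). Neutrophil S100a9 fell by 3.13 ± 0.64. The microglia RNA list fell with 3 of 10 down over the list alone (0 over all genes, camera adjusted p = 0.0358, and adjusted p = 0.180 with an estimated correlation), and B cell RNA (adjusted p = 0.616), naive T genes (0.202) and sex-linked genes (0.747) did not pass.

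In edgeR 385 of 11174 genes differed between microglia-like cells of control tumours and healthy brain (341 up, 44 down, DESeq2 580), and 49.6% of genes had non-overlapping libraries, against 33.3% expected by chance for 2 against 2. Scaling by library size alone, under which the median of all genes stood at log2 -0.13, gave 287 up and 87 down. The 2 healthy libraries fell mostly into different microglia-like clusters. Of the class in healthy replicates 1 and 2, 1 cluster held 60.0% and 1.3% and another 1.6% and 64.1%. Clustering used no correction between libraries. The cluster led by Csf1, Egr3 and Tnf held 37.8% and 46.6% of the class in control tumours and 0.0% and 0.1% in healthy brain. It was the 1 named cluster with no marker of its own class among its 10 leading genes, so its name is less certain. Without it 24 genes were called, 18 of them shared with the 385. Gbp2 (log2 4.15), Ifi204 (3.30), Axl (2.88), Bst2 (1.76), Tap1 (2.0), Psmb9 (1.61), Pdcd1 (3.18) and Ddit4 (-2.46) stayed past the threshold, while H2-Aa (7.14, adjusted p = 0.145) and Cd74 (6.17, adjusted p = 0.178) did not. Gbp4 (4.45), Iigp1 (4.45), Gbp8 (3.43), Cd36 (2.41), Ms4a4c (2.33), H2-Oa (1.85), Gbp5 (1.63), Plac8 (0.91), Myo18b (-0.98) and Lrba (-0.75) were not called there either. Serpina3f (8.98), Il1rn (4.99), H2-Ab1 (4.85), Nlrc5 (4.59), Oasl1 (2.97), C3 (2.68) and Pfkp (2.51) lost their calls too. So did Klrk1 (2.48), Nkg7 (2.41), Isg15 (2.09), Clec7a (1.99), Itgax (1.81) and Plin2 (1.03). Among the falls the same held for S100a9 (-3.69), Mycl (-1.53), Mboat1 (-1.43), Ccdc80 (-1.23), Jam3 (-1.05), Tmem44 (-1.0) and Acvr2b (-0.94). Sox4 (-0.84, adjusted p = 0.116) was not called with the library split as a batch, nor C4b (7.06, adjusted p = 0.0581) with mixed barcodes called at the higher level. Both were also lost without the Csf1-led cluster, Sox4 at -0.95 (edgeR adjusted p = 0.278) and C4b at 5.22 (0.354). The count was 177 without control replicate 1, 161 without control replicate 2, 592 without Rbpj-deleted replicate 1 and 661 without Rbpj-deleted replicate 2.

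Monocyte/macrophage-like cells of control tumours carried more interferon-gamma response and class I presentation RNA than those of healthy brain (camera adjusted p = 3.94e-48 and 5.69e-33). With an estimated correlation camera gave adjusted p = 0.0401 and 0.0250. Cxcl9, a chemokine that draws T cells (ENSMUSG00000029417, chromosome 5:92321347-92328079), rose by log2 9.80 ± 0.65 (SE, n = 2 libraries per group), from 3.776 to 3292 CPM. Acod1, which makes itaconate (ENSMUSG00000022126, chromosome 14:103046977-103056573), had 442 UMIs against 0, at least 379-fold higher, and the chemokine gene Cxcl11 279 against 0, at least 239-fold higher. Il12b, the shared subunit of interleukins 12 and 23 (ENSMUSG00000004296, chromosome 11:44400063-44414033), had 338 UMIs against 1 (870-fold, counting interval 155 to 34450), and the guanylate-binding protein genes Gbp2b 1451 against 2 (1867-fold, 516 to 15430) and Gbp11 114 against 1 (293-fold, 51.6 to 11690). Cxcl13, a chemokine for B cells, had 159 against 1 (409-fold, 72.4 to 16260) and AA467197 401 against 1 (1032-fold, 184 to 40850). Serpina3f rose by log2 8.49 ± 0.64 and Ly6a by 7.81 ± 0.87, the latter uncertain because 23.3% of its 31-mers are shared. Egfl7 fell by log2 3.54 ± 0.42, the endothelin receptor gene Ednrb by 3.23 ± 0.62 and Ddit4 by 3.09 ± 0.53, with Cd209b (4.25 ± 0.88), Lbx1 (4.01 ± 0.52), Hist1h3d (2.71 ± 0.59), Gfra2 (2.64 ± 0.41), Egfr (2.62 ± 0.44) and Epor (2.52 ± 0.35). With the library split as a batch AA467197 (log2 9.56, adjusted p = 0.0503), Gbp11 (7.70, 0.0693), Egfr (-2.36, 0.0581), Ddit4 (-3.13, 0.0818), Cd209b (-3.32, 0.0818) and Hist1h3d (-2.82, 0.104) were not called. Cd209b (-4.84, 0.0625) and Hist1h3d (-2.43, 0.149) were not called either with mixed barcodes called at the higher level.

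Of the interferon-gamma list 19 of 20 genes rose in these cells (adjusted over the list alone, 17 over all genes, camera adjusted p = 3.94e-48), among them Cd274, which encodes the checkpoint ligand PD-L1 (log2 4.13 ± 0.37). Class I presentation had 14 of 16 up (adjusted over the list alone, 13 over all genes, camera adjusted p = 5.69e-33). H2-Q7 stood at 4.72 ± 0.31. Class II presentation had 9 of 12 up (adjusted over the list alone, 6 over all genes, camera adjusted p = 1.38e-19, and adjusted p = 0.0250 with an estimated correlation). H2-Ab1 stood at 5.93 ± 0.50, H2-Aa at 5.52 ± 0.54 and Cd74 at 5.35 ± 0.55. The type I interferon list had 16 of 27 up (adjusted over the list alone, 7 over all genes, camera adjusted p = 4.10e-13, and adjusted p = 0.260 with an estimated correlation). Isg15 stood at 3.73 ± 0.48. Inflammatory cytokines had 14 of 20 up (adjusted over the list alone, 7 over all genes, camera adjusted p = 2.24e-15, and adjusted p = 0.0757 with an estimated correlation). Ccl5 stood at 7.06 ± 0.50, Il1b at 4.99 ± 0.70 and Cxcl10 at 3.26 ± 0.50. Disease-associated genes had 9 of 23 up and 1 down (adjusted over the list alone, 6 up over all genes, camera adjusted p = 1.40e-05, and adjusted p = 0.0757 with an estimated correlation). Itgax stood at 3.43 ± 0.38, Fabp5 at 2.96 ± 0.30 and Axl at 2.76 ± 0.24. Hypoxia and glycolysis genes had 11 of 15 up (adjusted over the list alone, 2 over all genes, camera adjusted p = 3.08e-07, and adjusted p = 0.260 with an estimated correlation). Hilpda stood at 2.24 ± 0.38 (2.0, adjusted p = 0.0778 with the library split as a batch), and Vegfa, which encodes an angiogenic factor, rose by 4.63 ± 0.49.

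RNA of T and NK cells rose in the same cells: 9 of 12 cytotoxicity genes were up (adjusted over the list alone, 5 over all genes, camera adjusted p = 6.11e-16, and adjusted p = 0.0757 with an estimated correlation), Klrk1 by log2 5.42 ± 0.41 and Ifng, which encodes interferon gamma itself, with 25 UMIs against 2 (32.2-fold, counting interval 8.02 to 280). Ifng was not called with mixed barcodes called at the higher level (log2 6.46, adjusted p = 0.0847) or with the library split as a batch (4.91, 0.0573). Exhaustion genes had 6 of 13 up (adjusted over the list alone, 3 over all genes, camera adjusted p = 0.000149, and adjusted p = 0.260 with an estimated correlation). Nr4a2 stood at 3.90 ± 0.53 (3.98, adjusted p = 0.0698 with the library split as a batch). The monocyte RNA list rose with 0 of 9 genes called singly (camera adjusted p = 0.0114, and adjusted p = 0.583 with an estimated correlation). The homeostatic microglia list fell with 2 of 19 down (adjusted over the list alone, 2 over all genes, camera adjusted p = 0.00144, and adjusted p = 0.583 with an estimated correlation). Microglia RNA fell with 1 of 9 down (camera adjusted p = 0.0403, and adjusted p = 0.583 with an estimated correlation). Complement (camera adjusted p = 0.0166, and adjusted p = 0.222 with an estimated correlation) and lipid handling genes (camera adjusted p = 0.0182, and adjusted p = 0.320 with an estimated correlation) rose as lists. Neutrophil RNA (adjusted p = 0.299), the cell cycle list (0.423), the sex-linked list (0.531) and the stress list (0.816) did not pass. The class differed in make-up: of 3 clusters named border macrophage, 1 held 78.5% and 71.7% of it in healthy brain and 11.3% and 9.8% in control tumours, and another 8.8% and 9.9% against 2.4% and 4.9%. The border cluster led by Ccl8 and Gbp2b held 0.0% and 1.3% in healthy brain and 23.1% and 51.2% in control tumours, and a monocyte-derived cluster 1.5% and 7.3% against 57.5% and 31.7%. Lyve1 and Cd163, which named the border clusters, are for that reason not given as results. In edgeR 433 of 11057 genes differed (331 up, 102 down, DESeq2 864, 52.9% of genes with non-overlapping libraries, 33.3% by chance). Library size alone, with the median of all genes at log2 -0.33, gave 240 up and 226 down. Without all 3 border clusters 741 were called, 279 of them shared with the 433. With the library split as a batch 177 were called (145 shared), and with mixed barcodes called at the higher level 287. The count was 124 without healthy replicate 1, 250 without healthy replicate 2 and 189 without control replicate 1.

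Between Rbpj-deleted and control tumours, microglia-like cells differed in 5 genes. Il12b rose by log2 4.02 ± 0.48 (SE, n = 2 libraries per group), from 1.09 to 17.96 CPM, and Fgr, a Src family kinase gene (ENSMUSG00000028874, chromosome 4:132974095-133001910), by 2.62 ± 0.35, from 5.661 to 34.27 CPM. Itgax, which encodes CD11c (ENSMUSG00000030789, chromosome 7:128129547-128150657), rose by 2.10 ± 0.27, from 37.15 to 157.1 CPM. Serpina3f fell by 2.29 ± 0.28, from 55.39 to 11.0 CPM, and the Y-linked RNA helicase gene Ddx3y by 2.05 ± 0.25, from 89.58 to 22.36 CPM. All 5 had edgeR adjusted p = 0.0152.

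The disease-associated list stood higher in microglia-like cells of Rbpj-deleted than of control tumours, with 12 of 23 up (adjusted over the list alone, 1 over all genes, camera adjusted p = 6.50e-14, and adjusted p = 0.184 with an estimated correlation). Beside Itgax, Clec7a stood at log2 1.52 ± 0.30, Axl at 1.2 ± 0.25 and the tetraspanin gene Cd9 at 0.81 ± 0.20, none past the test over all genes. The type I interferon list was higher with 4 of 27 up (adjusted over the list alone, 0 over all genes, camera adjusted p = 5.39e-07, and adjusted p = 0.184 with an estimated correlation), Ifit3 at 0.80 ± 0.19 and Irf7 at 0.89 ± 0.22. The interferon-gamma list was lower, with 6 of 19 down and 2 up (adjusted over the list alone, 1 up over all genes, Il12b; camera adjusted p = 0.00519, and adjusted p = 0.184 with an estimated correlation): Gbp4 stood at -2.11 ± 0.37, Iigp1 at -1.64 ± 0.29 and Gbp5 at -0.90 ± 0.21. The alternative activation list was higher with 1 of 16 up (adjusted over the list alone, 0 over all genes, camera adjusted p = 5.70e-05, and adjusted p = 0.184 with an estimated correlation), Spp1, which encodes osteopontin, at 3.80 ± 0.76 and Vegfa at 3.02 ± 0.63. Glycolysis genes were higher with 4 of 14 up (adjusted over the list alone, 0 over all genes, camera adjusted p = 0.000161, and adjusted p = 0.334 with an estimated correlation), Pkm at 1.12 ± 0.28 and Pgk1 at 1.04 ± 0.26. Lipid handling was higher with 4 of 20 up (adjusted over the list alone, 0 over all genes, camera adjusted p = 0.00519, and adjusted p = 0.535 with an estimated correlation). The cholesterol exporter gene Abcg1 stood at 1.36 ± 0.32. The homeostatic list was lower with 0 of 20 called (camera adjusted p = 0.00714, and adjusted p = 0.184 with an estimated correlation), as was the stress list with 0 of 20 (camera adjusted p = 0.00519, and adjusted p = 0.535 with an estimated correlation). The cell cycle list was higher with 0 of 19 called (camera adjusted p = 0.000222, and adjusted p = 0.345 with an estimated correlation). The sex-linked list was lower with 4 of 5 down (adjusted over the list alone, 1 over all genes, camera adjusted p = 5.105e-07, and adjusted p = 0.184 with an estimated correlation). Microglia RNA was lower too, with 0 of 10 called (camera adjusted p = 0.0132, and adjusted p = 0.184 with an estimated correlation). Monocyte RNA was higher with 2 of 5 up over the list alone (camera adjusted p = 0.00519, and adjusted p = 0.184 with an estimated correlation), Fn1 at 6.81 ± 1.54, and the cytotoxicity list with 0 of 9 called (camera adjusted p = 0.00852, and adjusted p = 0.275 with an estimated correlation). The class I list (adjusted p = 0.280), the class II list (0.134), the cytokine list (0.134), the complement list (0.318) and the Notch list (0.421) did not pass.

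Of 11174 genes 1379 had unadjusted p under 0.05 in this comparison, and DESeq2 called 149. In all, 46.4% of genes had non-overlapping libraries (33.3% by chance). The Csf1-led cluster held 63.4% and 14.3% of microglia-like cells in the Rbpj-deleted libraries, and a cluster led by Spp1, Apoc1 and Cd9 23.1% and 70.8%, against 30.5% and 22.2% in control tumours. Without the Csf1-led cluster 0 genes were called, with Itgax at log2 2.02 (adjusted p = 0.0735), Fgr at 2.99 (0.0844), Ddx3y at -0.99 (0.163) and Serpina3f at -0.28 (0.927). Il12b had no value in that fit. The count was 0 without control replicate 1 and 0 without control replicate 2, 379 without Rbpj-deleted replicate 1, 20 without Rbpj-deleted replicate 2, 160 without healthy replicate 1 and 184 without healthy replicate 2. In a fit of these 2 groups alone 145 were called. With the library split as a batch 25 were called, of the 5 Ddx3y alone: Itgax stood at log2 2.08 (adjusted p = 0.0791), Fgr at 2.12 (0.122), Il12b at 3.70 (0.550) and Serpina3f at -2.28 (1.0).

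**Figure D2:**
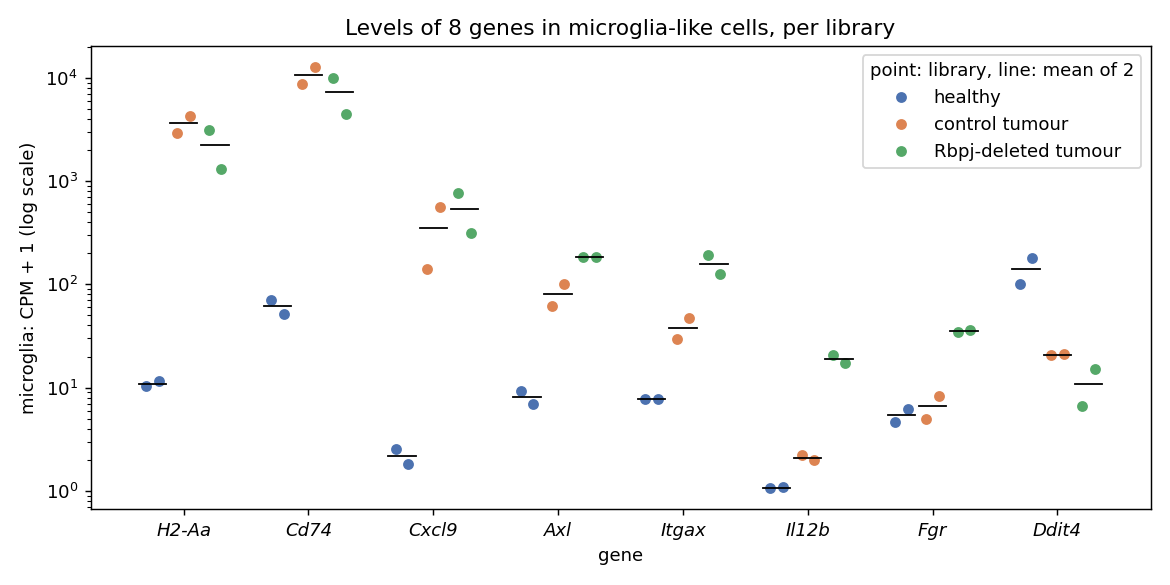
CPM + 1 (log scale, vertical axis) of 8 genes in microglia-like cells; points are libraries and lines are means of 2 libraries. H2-Aa averages 9.918 CPM in healthy brain, 3615 in control tumours and 2214 in Rbpj-deleted tumours, and Itgax 6.74, 37.15 and 157.1.

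In monocyte/macrophage-like cells the interferon-gamma list was lower in Rbpj-deleted than in control tumours, with 18 of 20 genes at negative values and 0 called (camera adjusted p = 1.07e-05, and adjusted p = 0.461 with an estimated correlation). The nitric oxide synthase gene Nos2 stood at log2 -1.78 ± 0.43 (SE, n = 2 libraries per group), Gbp4 at -1.57 ± 0.41 and Il12b at -1.94 ± 0.67. The cell cycle list was higher with 1 of 19 up over the list alone (camera adjusted p = 4.90e-05, and adjusted p = 0.180 with an estimated correlation), Birc5, which encodes survivin, at 3.83 ± 0.64. The type I interferon list was higher (camera adjusted p = 0.0154, and adjusted p = 0.828 with an estimated correlation) and the cytokine list lower (camera adjusted p = 0.0435, and adjusted p = 0.791 with an estimated correlation), each with 0 called. The stress list was lower too (camera adjusted p = 0.0242, and adjusted p = 0.791 with an estimated correlation), and neutrophil RNA higher with S100a9 at 3.46 ± 0.75 (camera adjusted p = 0.0189, and adjusted p = 0.454 with an estimated correlation). The sex-linked list was lower with 4 of 5 down over the list alone (camera adjusted p = 2.63e-18, and adjusted p = 0.0776 with an estimated correlation), Ddx3y at -2.47 ± 0.25. No single gene passed: edgeR called 0 of 11057 (468 at unadjusted p under 0.05, smallest adjusted p = 0.0703, Ddx3y), DESeq2 19, and 31.1% of genes had non-overlapping libraries, against 33.3% by chance. The monocyte-derived cluster held 27.2% and 72.8% of the class in the Rbpj-deleted libraries and the Ccl8-led border cluster 65.3% and 20.4%. The count was 20 without healthy replicate 1, 21 without healthy replicate 2, and 1 without control replicate 1, control replicate 2 or Rbpj-deleted replicate 1.

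A direct test of whether the Rbpj contrast differed between monocyte/macrophage-like and microglia-like cells gave 0 of 11755 genes by limma, with 877 at unadjusted p under 0.05. Il12b stood at log2 -5.75 ± 0.73 (adjusted p = 0.121) and Itgax at -1.68 ± 0.28 (adjusted p = 0.299), so the opposite signs of Il12b in the 2 classes were not called as a difference. The smallest adjusted p was 0.0636, shared by the cytoskeletal gene Actn1 (log2 2.32 ± 0.23) and the neutrophil chemokine gene Cxcl2 (-3.03 ± 0.31). The count was 15 without control replicate 1, 43 without control replicate 2 and 1 without healthy replicate 1.

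T-like cells, which formed 1 cluster led by Cd3g, Trac and Cd8a, differed between Rbpj-deleted and control tumours in 25 of 7098 genes (17 up, 8 down). Gzma, a granzyme of cytotoxic lymphocytes (ENSMUSG00000023132, chromosome 13:113093825-113100981), rose by log2 3.35 ± 0.39 (SE, n = 2 libraries per group), from 117.3 to 1204 CPM, with the NK receptor gene Klra3 (3.13 ± 0.40) and the steroid-metabolising enzyme gene Akr1c18 (7.43 ± 0.82). Gzma is also in the NK marker set, and T and NK cells counted as 1 lineage when mixed barcodes were removed. NK RNA in this cluster was thus not told apart from a change in T-like cells. Gldc, a glycine cleavage enzyme gene, fell by 3.74 ± 0.55, Ociad2 by 2.83 ± 0.45, and the tropomyosin gene Tpm3 by 2.19 ± 0.23. The Y-linked genes Ddx3y and Eif2s3y fell by 4.23 ± 0.59 and 3.05 ± 0.49. Class II presentation had 6 of 9 up (adjusted over the list alone, 1 over all genes, H2-Eb1 at 5.75 ± 0.37, camera adjusted p = 2.48e-15, and adjusted p = 0.339 with an estimated correlation). H2-Eb1 also stood higher by log2 5.99 in microglia-like and 5.65 in monocyte/macrophage-like cells of the Rbpj-deleted libraries. Myeloid RNA in the T-like cluster was thus not told apart from a change in T-like cells. H2-T22 of the class I list rose by 5.63 ± 0.33 (3 of 16 up over the list alone, camera adjusted p = 0.000252, and adjusted p = 0.499 with an estimated correlation). Gzma was the 1 called gene of the 14 cytotoxicity genes (camera adjusted p = 0.379). The exhaustion list was lower with 0 of 17 called (camera adjusted p = 0.00176, and adjusted p = 0.354 with an estimated correlation): Pdcd1, which encodes PD-1, stood at -0.91 ± 0.24 and Ctla4 at -0.59 ± 0.24. The type I interferon list was higher with 4 of 19 up over the list alone (0 over all genes, camera adjusted p = 3.97e-05, and adjusted p = 0.366 with an estimated correlation).

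Myeloid and stress RNA moved with these T-like cells: C1qa (log2 1.93 ± 0.24), C1qc (1.77 ± 0.25), C1qb (1.51 ± 0.22) and Lyz2 rose. The homeostatic microglia list was higher with 1 of 9 up over the list alone (camera adjusted p = 3.97e-05, and adjusted p = 0.354 with an estimated correlation). The dissociation and stress list was higher with 1 of 20 up over the list alone (0 over all genes, camera adjusted p = 0.000179, and adjusted p = 0.354 with an estimated correlation). The disease-associated list was higher with 3 of 17 up over the list alone (0 over all genes, camera adjusted p = 0.000295, and adjusted p = 0.354 with an estimated correlation). With mixed barcodes called at the higher level 0 of the 25 were called and C1qa stood at -0.57, while Gzma stood at 3.33, Klra3 at 3.16, Akr1c18 at 7.46, H2-T22 at 5.58, Gldc at -3.94 and Ddx3y at -3.46. H2-Eb1 stood at 4.41 in that setting. Of the 25, 13 belong to the set of 39 genes that separate the same tumour libraries alike in the myeloid classes, and were chosen for that: H2-T22, H2-Eb1, H2-Ea-ps, H2-K2, Rps3a2, Rpl29, Tpm3, Tpm3-rs7, Trim5, Trim12a, Trim30d, Ddx3y and Ctse. Several are counted against few UMIs: Trim5 23 against 1 (95.7-fold, counting interval 15.5 to 3941), Trim30d 37 against 2 (77.0-fold, 19.9 to 659), Trim12a 43 against 3 (59.6-fold, 19.1 to 300) and Ctse 193 against 2 (23.2-fold lower, 6.34 to 193). H2-T22 (47.7%), Tpm3-rs7 (61.9%), Trim5 (36.7%), Klra3 (57.4%), Rps3a2 (88.3%), Rpl29 (57.7%) and H2-K2 (20.7%) share these percentages of their 31-mers with other genes, so their values are uncertain. In edgeR 554 genes had unadjusted p under 0.05, DESeq2 called 46, and 38.1% of genes had non-overlapping libraries (33.3% by chance). The count was 88 without control replicate 1, 59 without control replicate 2, 15 without Rbpj-deleted replicate 1 and 6 without Rbpj-deleted replicate 2.

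Against healthy brain, microglia-like cells of Rbpj-deleted tumours also carried more interferon response and class I presentation RNA (camera adjusted p = 9.90e-62 for the type I interferon, 3.04e-37 for the interferon-gamma and 7.90e-30 for the class I list). With an estimated correlation camera gave adjusted p = 0.0394, 0.0394 and 0.0474 in the same order. Cxcl9 rose by log2 8.73 ± 1.29 (SE, n = 2 libraries per group), H2-Aa by 7.81 ± 0.54, Cd74 by 6.90 ± 0.49, the endonuclease gene Dnase1l3 by 6.95 ± 0.46 and Il1rn, the interleukin 1 receptor antagonist gene, by 6.49 ± 0.62. Acod1 had 500 UMIs against 1 (1538-fold, counting interval 275 to 60880), Cxcl13 451 against 1 (1388-fold, 248 to 54930) and Il12b 236 against 3 (242-fold, 81.8 to 1182). Spp1 rose by 5.62 ± 0.82, Axl by 4.67 ± 0.28, Itgax by 4.55 ± 0.29, Clec7a by 3.76 ± 0.33 and the ferritin gene Fth1 by 2.08 ± 0.24. Ddit4 fell by 3.95 ± 0.49, Mycl by 3.04 ± 0.26, and the glucocorticoid-induced genes Fkbp5 and Tsc22d3 by 2.63 ± 0.34 and 2.25 ± 0.23. Sema4b (2.16 ± 0.26), Jam3 (2.09 ± 0.24), Csmd3 (2.06 ± 0.29), Myo18b (2.01 ± 0.24) and Peg10 (1.90 ± 0.33) fell as well. With the library split as a batch Cxcl9 (log2 9.35, adjusted p = 0.192), Acod1 (11.44, adjusted p = 0.0838) and Spp1 (5.63, adjusted p = 0.178) were not called. Without the Csf1-led cluster Spp1 (5.71, adjusted p = 0.0674) and Csmd3 (-1.66, adjusted p = 0.0908) were not called.

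Of the type I interferon list all 27 genes rose in this contrast (adjusted over the list alone, 25 over all genes, camera adjusted p = 9.90e-62). Of the interferon-gamma list 18 of 19 rose (adjusted over the list alone, 15 over all genes, camera adjusted p = 3.04e-37), as did 15 of 16 of the class I list (adjusted over the list alone, 14 over all genes, camera adjusted p = 7.90e-30). The disease-associated list had 18 of 23 up (adjusted over the list alone, 14 over all genes, camera adjusted p = 7.14e-21, and adjusted p = 0.0753 with an estimated correlation). Class II presentation had 8 of 12 up (adjusted over the list alone, 5 over all genes, camera adjusted p = 1.16e-11, and adjusted p = 0.0753 with an estimated correlation). Cell cycle genes had 14 of 19 up (adjusted over the list alone, 11 over all genes, camera adjusted p = 4.37e-10, and adjusted p = 0.106 with an estimated correlation). Mki67 stood at 3.99 ± 0.57. Homeostatic genes had 8 of 20 down (adjusted over the list alone, 5 over all genes, camera adjusted p = 1.16e-05, and adjusted p = 0.0677 with an estimated correlation): Ltc4s by 0.95 ± 0.22, beside Tmem119, Selplg and Cx3cr1, which named the class. Without the Csf1-led cluster none of these 4 was called: Ltc4s stood at -0.51 (adjusted p = 0.131), Tmem119 at -0.71 (0.0887), Selplg at -0.73 (0.0946) and Cx3cr1 at -0.69 (0.0805). With the library split as a batch Ltc4s (-0.84, adjusted p = 0.0608), Tmem119 (-0.86, 0.0583) and Cx3cr1 (-0.87, 0.0556) were not called. Monocyte RNA rose with 4 of 5 up (camera adjusted p = 1.97e-10, and adjusted p = 0.0474 with an estimated correlation), Fn1 by 5.86 ± 0.99. Cytotoxicity RNA rose with 8 of 9 up over the list alone (camera adjusted p = 5.90e-09, and adjusted p = 0.0753 with an estimated correlation). Fn1 was not called without the Csf1-led cluster (5.99, adjusted p = 0.107) or with the library split as a batch (5.69, 0.213). Microglia RNA was lower with 4 of 10 down (adjusted over the list alone, 2 over all genes, camera adjusted p = 0.00118, and adjusted p = 0.0753 with an estimated correlation). The sex-linked list was lower with 4 of 5 down (adjusted over the list alone, 3 over all genes, camera adjusted p = 0.00217, and adjusted p = 0.106 with an estimated correlation). The cytokine list had 15 of 19 up (adjusted over the list alone, 6 over all genes, camera adjusted p = 2.58e-14, and adjusted p = 0.0753 with an estimated correlation). In edgeR 1324 of 11174 genes differed (899 up, 425 down, DESeq2 1479, 57.8% of genes with non-overlapping libraries, 33.3% by chance). Library size alone, with the median of all genes at log2 -0.24, gave 702 up and 1030 down. The Csf1-led cluster held 63.4% and 14.3% of the class in Rbpj-deleted tumours and 0.0% and 0.1% in healthy brain, and the Spp1-led cluster 23.1% and 70.8% against 6.5% and 7.5%. An equal number of cells per library gave 662 calls, and the library split as a batch 1073 (883 shared with the 1324).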

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

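All tests in this part were chosen only after the results were seen. Barcodes with RNA of 2 lineages were 22.49% and 33.6% of the control tumour libraries and 24.07% and 23.57% of the Rbpj-deleted libraries, against 11.41% and 6.318% in healthy brain. Most paired a myeloid lineage with T or NK cells (1631 barcodes) or with B cells (522), and they had 1.71 to 3.5 times the counts of other barcodes. The number of barcodes loaded cannot be told apart: given the lineages present, 3 tumour libraries with fewer barcodes than healthy replicate 1 would need a higher share of pairs (53.5% to 62.2% against 46.5%), but control replicate 1 a lower one (39.7%). Free RNA in the droplets cannot be told apart from joined cells: the second lineage had a median of 0.138 to 0.224 of its own level. Random pairing of 2 captured cells would need 31.9% to 62.2% of a library's barcodes to be pairs. The highest share was that of control replicate 2, with 756 barcodes against 7181 in healthy replicate 1. The rate of pairs was not measured, so random pairing cannot be told apart either.

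The unnamed cluster led by Ighg2b, Mki67 and Top2a held 2.743% and 4.382% of kept cells in control tumours and 3.881% and 9.831% in Rbpj-deleted tumours, against 0.173% and 0.331% in healthy brain. Its 331 cells are in no class and were not analysed here.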

How the results depend on the processing

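The library split, index-hopped, higher mixed level, mixed-cluster, Csf1-cluster, low-UMI and all between-class settings were chosen only after the results were seen; the others were set before the data were examined. Of 223 alternative counts 153 stayed within 1.5 times and 70 moved. Of 5940 values of named genes and shares 5361 stayed called or stayed uncalled, 552 lost a call, 9 gained one and 18 turned. Of 227 pairs of a called named gene and a contrast, 84 passed in every setting that gave them a value. The cause was not tested. A planned setting had no value where no microglia cluster was led by cycle genes, where the single T cluster was the CD8 one, where healthy libraries were not in the T fit, and for classes under 20 cells per library.

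Shares called from healthy brain to control tumours (1) became 2 by limma, 3 by TMM, 2 with the library split as a batch, and 0 (without healthy replicate 1) to 3 (without control replicate 2; 2 without healthy replicate 2) on leaving out a library. Shares from healthy brain to Rbpj-deleted tumours (0) became 1 at Leiden resolution 2, 1 with mixed clusters removed and 1 without healthy replicate 2.

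Microglia calls from healthy brain to control tumours (385) became 24 without the Csf1-led cluster, 580 by DESeq2, 786 unfiltered, 604 with 2 groups, and 161 (without control replicate 2; 177 without control replicate 1) to 661 (without Rbpj-deleted replicate 2; 592 without its replicate 1). The 5 microglia calls between tumours became 2 with doublets kept, 0 without the Csf1-led cluster, 149 by DESeq2, 384 unfiltered, 145 with 2 groups, 25 with the library split as a batch (1 shared), and 0 (without either control library) to 379 (without Rbpj-deleted replicate 1; 20 without its replicate 2; 160 and 184 without healthy replicates 1 and 2). The 1324 against healthy brain became 662 with equal cells, 2016 unfiltered, 881 with 2 groups, and 924 (without control replicate 2) to 1715 (without Rbpj-deleted replicate 1).

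Monocyte/macrophage calls from healthy brain to control tumours (433) became 287 at the higher mixed level, 706 with mixed clusters removed, 741 without border clusters, 864 by DESeq2, 1374 unfiltered, 177 with the library split, and 124 (without healthy replicate 1; 250 without its replicate 2; 189 without control replicate 1) to 579. The 0 between tumours became 1 at Leiden resolution 0.5, 1 with mixed clusters removed, 4 without border clusters, 19 by DESeq2, 88 unfiltered, 14 with 2 groups, 20 and 21 without healthy replicates 1 and 2, and 1 without control replicate 1, control replicate 2 or Rbpj-deleted replicate 1, the range being 0 to 21. The 25 T-like calls became 0 at the higher mixed level, 46 by DESeq2, 190 unfiltered, and 6 (without Rbpj-deleted replicate 2; 15 without its replicate 1) to 88 (without control replicate 1; 59 without its replicate 2). The 0 between classes became 3 with at least 1000 genes, 3 with at most 5% mitochondrial counts, 3 with mixed clusters removed, 1 without healthy replicate 1, 15 without control replicate 1 and 43 without control replicate 2, the range being 0 to 43. Of 75 list calls 10 stayed with an estimated correlation and 36 by fry, which called 37.

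Whether replicate numbers pair the libraries is not known. Differences of replicate 2 from 1 correlated at 0.02, -0.05 and -0.09 between groups in microglia-like cells and -0.29, 0.25 and -0.43 in monocyte/macrophage-like cells. Such values do not exclude shared processing, as libraries of a group also differed in their make-up of clusters. With the replicate block shares from healthy brain to control tumours had 2 calls, microglia calls were 409, 33 and 1215, monocyte/macrophage calls 252 and 0, T-like calls 20, between-class calls 0 and list calls 75; the other share contrasts stayed at 0.

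Directions turned for shares not called: B-like cells from healthy brain to control tumours (log2 -0.51 with doublets kept, -1.34 by TMM, -0.41 without control replicate 1, up to 1.9 without healthy replicate 2) and to Rbpj-deleted tumours (0.17 at 5% mitochondrial counts, 0.25 without healthy replicate 2, down to -1.85 without Rbpj-deleted replicate 2), monocyte/macrophage-like cells from healthy brain to control tumours (-1.61 by TMM), and between tumours dendritic-like cells (-0.02 at 5% mitochondrial counts, -0.02 with doublets kept, -0.46 with the library split, -0.44 without control replicate 2, -0.33 without Rbpj-deleted replicate 1, up to 0.79 without control replicate 1) and microglia-like cells (-0.20 without control replicate 1, -0.31 without Rbpj-deleted replicate 1, up to 0.63 without control replicate 2). Among named genes Ccl7 turned to -0.10 in microglia-like cells of control tumours without the Csf1-led cluster, S100a9 to 0.60 in those of Rbpj-deleted tumours with index-hopped copies kept, and C1qa, C1qc and C1qb to -0.57, -0.66 and -0.72 in T-like cells at the higher mixed level.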

Other observations

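The tests of the library split and of the Csf1-led cluster were chosen only after the results were seen. In microglia-like cells of Rbpj-deleted tumours Top2a stood at log2 3.97 ± 0.40, Cdk1 at 1.59 ± 0.26 and Mcm5 at 1.98 ± 0.29 against healthy brain (SE, n = 2 libraries per group). In monocyte/macrophage-like cells of control tumours Top2a rose by 2.12 ± 0.32 and Mki67 by 2.52 ± 0.47, while Cenpf fell by 1.93 ± 0.33. The cell cycle list did not pass in that contrast (camera adjusted p = 0.423), and with the library split as a batch Top2a (2.10, adjusted p = 0.0581), Mki67 (2.58, 0.101) and Cenpf (-1.69, 0.0728) were not called. Glycolytic Pgk1 and Hilpda rose by 1.49 ± 0.26 and 1.67 ± 0.30 in microglia-like cells of Rbpj-deleted tumours against healthy brain, where their list had 9 of 14 up (adjusted over the list alone, 8 over all genes, camera adjusted p = 9.135e-07, and adjusted p = 0.152 with an estimated correlation). Hilpda was not called without the Csf1-led cluster (1.16, adjusted p = 0.0650).

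A set of 39 of 9203 genes separated the control from the Rbpj-deleted libraries alike in microglia-like and monocyte/macrophage-like cells, among them H2-T22, H2-Eb1, the Tpm3 pair and Ddx3y. On 26 of the 39 the 2 healthy libraries differed in the same direction by at least 0.5 times as much. Deletion of Rbpj in the tumour does not account for that healthy difference. A further effect of the deletion on these genes is not excluded, and how often other genes meet this rule was not counted. For the other 13, Ddx3y among them, deletion of Rbpj cannot be told apart from other causes. Of the set 17 lay within 1 Mb of another member, and random sets had a median of 2. The one-sided permutation p was 0.0001, the smallest that 10000 draws can give. A genetic background shared by healthy replicate 2 and the Rbpj-deleted pools could give this. Most of these genes lie in 1 stretch of chromosome 17, from H2-K2 to H2-T22, and Trim5, Trim12a and Trim30d lie together on chromosome 7. The random sets drew genes singly, so the p-value does not allow for neighbours that are regulated together or share sequence. Of the set 48.7% shared 31-mers with another gene (other genes 6.5%, Fisher p = 6.44e-13), which reads divided between near-identical copies could give. Split into 3 and 3, the libraries parted in 22 genes as healthy replicate 1 with the controls against healthy replicate 2 with the Rbpj-deleted ones, and in 3 or fewer genes any other way.

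The microglia-like cluster led by Csf1, Egr3 and Tnf may hold cells that responded to handling. Over all microglia-like cells, the stress list was above both healthy libraries in 3 tumour libraries (mean log2 10.22, 10.34 and 10.08 against 9.89 and 9.78). In Rbpj-deleted replicate 2 (9.02) it was below them. There the cluster held 14.3% of the class, against 37.8%, 46.6% and 63.4% in the other tumour libraries. The list was not measured in the cluster itself, so a handling response during dissociation cannot be told apart. The cluster may also hold monocyte-derived cells, as no microglia marker was among its 10 leading genes. In it 7 homeostatic genes not used for naming were 2.48 to 5.01 times higher than in the monocyte-derived cluster (median 3.165). They were not compared with the other microglia-like clusters, so this cannot be told apart either.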
